A study of Mus musculus with 9 samples.

How the data were processed

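RNA-seq was analysed for granulosa cells, the somatic cells that surround the oocyte in the ovarian follicle, from Kunming mice at postnatal day 21. Per the labels, the mice received 5 IU of PMSG (pregnant mare serum gonadotropin, which drives follicle growth). At 48 h after PMSG they received 5 IU of hCG (human chorionic gonadotropin, which acts on the LH receptor and triggers ovulation). Cells were taken at 0, 1 and 6 h after hCG, with 3 libraries per time and 9 in all. Per the labels' protocols, RNA was isolated with Trizol and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. No label says that the 3 libraries of a time came from separate animals or pools. Each p-value of a single gene therefore measures the spread between these libraries, which may be technical. P-values that set a group of genes against other genes take genes as the units. No library without hCG at a matched hour was analysed here, so time after hCG cannot be separated from time of day.

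The deposited tables give FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) for 54759 rows per library. HISAT2 2.0.5 and the mouse genome build mm10 are named in the submitters' processing notes. The program that made the FPKM values, its annotation and its filters are not given in the sources used here. The tables pair each row with a gene identifier, a symbol and a gene type but give no transcript name. There were 25059 gene identifiers, of which 11778 had more than 1 row and 784 were loci assembled outside the annotation. Between 9364 and 9682 rows per library lay above 0 but below 0.001 FPKM, so the low values are not whole multiples of a single read. Reads could not be recovered, the depth is unknown, and no counting interval or floor is given. An exact 0 may be a failed estimate rather than an absence of reads. The library protocol in the labels does not state whether strand was kept, so overlapping and antisense genes could share reads. The same holds for near-identical copies such as histone genes and pseudogenes.

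The FPKM of a gene was computed here as the sum of its rows. The 27 symbols stored as dates were restored from their identifiers. Where a symbol stood on more than 1 identifier, the entry with the highest mean kept the plain symbol. The identifier was added to the symbol of 39 other Ensembl entries. Of 24275 Ensembl identifiers, 23953 were found in GENCODE M21 (mm10), from which all coordinates were taken. The planned analysis allowed for counts or FPKM, and the FPKM branch was used. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trended prior variance. The 14535 genes with 1 FPKM or more in at least 3 libraries were tested. All 9 libraries entered a single fit of the 3 group means, with 6 residual degrees of freedom and no covariate. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Levels are given as mean FPKM ± SD (n = 3) and log2 changes with their SE.

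Before the data were examined, 27 gene lists were written from general knowledge of ovulation. They cover immediate-early factors, feedback regulators, ovulatory and matrix genes, steroid and cholesterol synthesis, and other processes. Further lists hold markers of oocytes, theca and stroma, endothelium, leukocytes, erythroid cells and surface epithelium, or signs of RNA and sample quality. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over 27 lists and 3 comparisons. Camera with an estimated correlation and fry were the alternatives. With the estimated correlation none of the 81 list tests stayed below an adjusted p of 0.05 (smallest 0.205), while 12 had an unadjusted p below it. The preset correlation called 36 and fry called 50. Fry asks whether the genes of a list move, on balance, in a single direction, and compares them with no other genes.

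Named genes were chosen by a rule fixed at the same stage. In each comparison it takes the 8 highest and 8 lowest changes among called genes with at least 5 FPKM in the higher group and all 3 libraries of either group above all 3 of the other. It adds 20 genes of a fixed list of ovulation genes and up to 3 called members of each other list with the largest change. Clone-type, predicted and assembled names were left out of the first part, and the exclusion was read to cover RP23, RP24, XLOC and CT names.

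On simulated data with 200 changed genes among 14535, the test recovered 92% of 2-fold and 99% of 4-fold changes in the 1 h against 0 h comparison, with 11 false calls. In the 6 h against 0 h comparison it recovered 90% and 99% with 8 false calls, and in the 6 h against 1 h comparison 92% and 100% with 7. The changed genes were drawn from those averaging 5 FPKM or more, so recovery of lower genes was not measured. Camera called 5 of 5 shifted sets and 0 of the other sets in simulated data for the 6 h against 0 h comparison. The simulated noise was independent between genes, so this does not show how camera behaves on lists of correlated genes. Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a fit of the 2 groups compared, the replicate number as a block, leaving out each library, a fold minimum of 2 and a limma treat test against a fold of 1.5. Added after the data were examined were median-ratio scaling, scaling of FPKM to a constant sum above that of the libraries, scaling to the mean sum of the libraries, quantile normalization, a filter of 1 FPKM in every library of a group, protein-coding genes alone and the most abundant row per gene. Alternatives that need counts were not run. Tables were built with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.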

Results

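Granulosa cell transcriptomes were measured at 3 times of gonadotropin-induced ovulation in mice. The groups were 0 h (PMSG for 48 h, no hCG yet), 1 h after hCG and 6 h after hCG, with 3 libraries each. Between 13587 and 13862 genes reached 1 FPKM or more in a library. The sum of FPKM was 493222 ± 1980 at 0 h, 551992 ± 22575 at 1 h and 526831 ± 12949 at 6 h (SD, n = 3 each). The depth in reads is unknown from these values. The series asks how the granulosa cell transcriptome changes between the hCG stimulus and ovulation.

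The libraries of a time resembled each other more than those of other times. Pearson's r across genes was 0.982 to 0.988 within a group and 0.874 to 0.972 between groups, where genes are not independent replicates. The first principal component held 65.9% of the variance and set the 6 h libraries apart, and the second held 17.5% and set the 1 h libraries apart. On the second component, replicate 2 at 1 h lay nearer to the 0 h libraries (−16.9) than replicates 1 (−30.6) and 3 (−35.6).

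**Figure D1:**
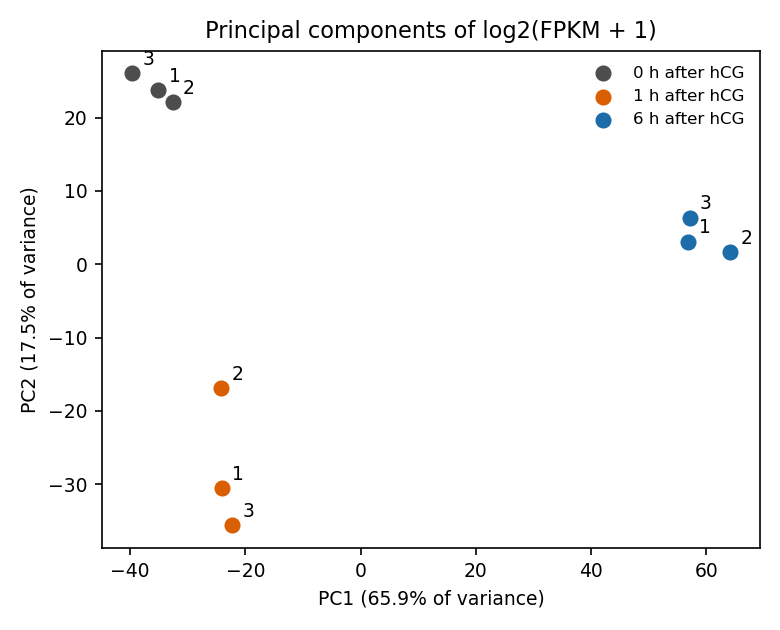
Principal components of log2(FPKM + 1) for the 14535 tested genes. Each point is a library, numbered by replicate and coloured by time after hCG, with the axes in component units. The 6 h libraries lie at 56.9 to 64.1 on the first component and all others below 0.

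The comparison of 1 h with 0 h describes the earliest response to hCG. The EGF-like growth factor genes *Ereg* and *Areg*, whose products relay the LH signal from mural to cumulus granulosa cells, had the 2 highest log2 changes. *Ereg* (ENSMUSG00000029377, chromosome 5, 91074622 to 91093646, mm10) went from 1.03 ± 0.293 to 309 ± 61.8 FPKM, a log2 change of 7.25 ± 0.19 (SE). *Areg* (ENSMUSG00000029378, chromosome 5, 91139599 to 91148432) went from 0.688 ± 0.257 to 173 ± 48.1 FPKM (6.66 ± 0.21). The orphan nuclear receptor gene *Nr4a1* (ENSMUSG00000023034) went from 33.0 ± 6.36 to 847 ± 242 FPKM and *Nr4a3* from 0.254 ± 0.118 to 66.5 ± 5.85. *Ptgs2*, the inducible prostaglandin synthase, rose from 0.712 ± 0.377 to 46.4 ± 13 FPKM. The tissue factor gene *F3* (log2 change 5.08), the stress-response gene *Gadd45b* (4.73) and the polo-like kinase gene *Plk2* (4.67) were also among the 8 highest that met the rule for naming, which leaves out predicted and assembled genes.

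Immediate-early transcription factors rose as a group at 1 h: 22 of 26 were called higher and 0 lower (24 higher adjusted over the list alone), with a median log2 change of 1.40. *Egr1* reached 606 ± 81.7 FPKM from 128 ± 16.1, whereas *Fos* was already at 181 ± 29.4 FPKM at 0 h and changed by 0.68 ± 0.13, a call that ended under quantile normalization (adjusted p = 0.117). For immediate-early factors the camera adjusted p was 7.90e-25, and the adjusted p was 0.205 with an estimated correlation. Feedback regulators of cAMP and MAP kinase signalling rose in 18 of 21 cases (19 adjusted over the list alone), among them the cAMP-responsive repressor gene *Crem* (4.29 ± 0.20) and the salt-inducible kinase gene *Sik1* (4.05 ± 0.23). For feedback regulators the camera adjusted p was 2.01e-17, with an adjusted p of 0.232 with an estimated correlation. Of 12 cyclin-dependent kinase inhibitor and growth arrest genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone). They included *Btg1* (2.63) and *Btg2* (2.60), with a camera adjusted p of 4.49e-05 and an adjusted p of 0.232 with an estimated correlation.

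Genes of the cumulus matrix and of ovulation had begun to rise. In the cumulus expansion list 8 of 11 members were higher and 0 lower (8 adjusted over the list alone), with a median log2 change of 2.52. The hyaluronan synthase gene *Has2* went from 0.713 ± 0.0614 to 9.18 ± 3.05 FPKM, the hyaluronan-linking *Tnfaip6* from 0.790 ± 0.443 to 16.1 ± 4.24, and *Ptx3* from 0.242 ± 0.148 to 6.33 ± 2.33. For cumulus expansion genes the camera adjusted p was 1.23e-07, and the adjusted p was 0.232 with an estimated correlation. Of 18 genes for factors required for ovulation 9 rose and 0 fell (11 adjusted over the list alone). The progesterone receptor gene *Pgr* (3.98 ± 0.15) and the protease gene *Adamts1* (2.77 ± 0.15) were among them, while *Runx1* measured 17.2 ± 3.81 and 23.6 ± 4.37 FPKM and did not pass (adjusted p = 0.0939), though it was called higher without 0 h replicate 2 (0.0374) or 1 h replicate 1 (0.0413). For the ovulatory factors the camera adjusted p was 2.88e-06, and the adjusted p was 0.232 with an estimated correlation. *Cebpb* rose from 21.9 ± 6.71 to 77.2 ± 15.8 FPKM, a call that ended without 1 h replicate 3 (adjusted p = 0.053). In the list of EGF-like factors and receptors 5 of 10 rose (5 adjusted over the list alone), with a camera adjusted p of 0.000481 and an adjusted p of 0.333 with an estimated correlation. *Btc* was at 8.77 ± 3.07 FPKM, from 1.17 ± 0.175.

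Steroidogenic genes changed in part. *Star*, which delivers cholesterol to the mitochondrion, went from 96.4 ± 10.5 to 308 ± 37.4 FPKM, and the electron donor gene *Fdx1* from 263 ± 71.7 to 1015 ± 156. *Cyp11a1* measured 857 ± 168 and 1143 ± 140 FPKM (adjusted p = 0.0829). In the progesterone list 4 of 14 rose (6 adjusted over the list alone), with a camera adjusted p of 0.00429 and an adjusted p of 0.333 with an estimated correlation. The aromatase gene *Cyp19a1* (ENSMUSG00000032274, chromosome 9, 54165937 to 54268110), which makes estradiol, rose from 191 ± 8.0 to 1074 ± 372 FPKM (2.42 ± 0.23, adjusted p = 0.000105). In its list, estradiol synthesis and FSH-dependent genes, 6 of 21 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.0902). The split was 4 higher and 2 lower with FPKM scaled to a constant sum, and 3 and 3 under quantile normalization with a median of −0.04. The member called lower, *Foxl2* (−0.71 ± 0.19), lost its call without 0 h replicate 1, 2 or 3, or without 1 h replicate 1 or 3 (adjusted p = 0.0617 to 0.0968), and with no filter on low values (0.0592). *Fshr*, at 93.0 ± 7.06 and 82.6 ± 13.5 FPKM, and *Lhcgr*, at 251 ± 28.5 and 337 ± 71.6 FPKM, did not pass (adjusted p = 0.323 and 0.194). *Fshr* was called lower with FPKM scaled to a constant sum (−0.34, adjusted p = 0.0354) and under quantile normalization (−0.38, 0.0223). *Nppc*, the natriuretic peptide precursor that holds the oocyte in meiotic arrest, rose from 115 ± 2.13 to 165 ± 14 FPKM. Cholesterol synthesis genes were higher in 7 of 23 cases (8 adjusted over the list alone), with a camera adjusted p of 0.00220 and an adjusted p of 0.576 with an estimated correlation. Of them 4 were higher with FPKM scaled to a constant sum, and their median of 0.18 became −0.02 under quantile normalization.

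Other lists with a camera call at 1 h were the unfolded protein response, heat shock, YAP targets, hypoxia and angiogenesis, proteases and reference genes. Unfolded protein response genes rose in 7 of 15 cases (8 adjusted over the list alone), led by *Dnajb9* (1.30) and *Ppp1r15a* (1.23), with a camera adjusted p of 3.17e-05 and an adjusted p of 0.333 with an estimated correlation. Heat-shock and dissociation stress genes, a sign of sample handling as well as of cell state, rose in 7 of 11 cases (8 adjusted over the list alone) but in 2 under quantile normalization, with *Bag3* at 1.28. For heat-shock genes the camera adjusted p was 3.17e-05, and the adjusted p was 0.287 with an estimated correlation. YAP targets rose in 5 of 9 cases (5 adjusted over the list alone), with *Amotl2* at 2.90 and *Cyr61* at 1.23. For YAP targets the camera adjusted p was 0.0131, and the adjusted p was 0.232 with an estimated correlation. In the hypoxia and angiogenesis list 4 of 18 rose (5 adjusted over the list alone), led by the prolyl hydroxylase gene *Egln3* (3.74), with a camera adjusted p of 0.0187 and an adjusted p of 0.308 with an estimated correlation. Proteases and inhibitors rose in 4 of 19 cases (5 adjusted over the list alone; camera adjusted p = 0.0345, adjusted p = 0.512 with an estimated correlation). Reference genes rose in 2 of 14 cases (3 adjusted over the list alone; camera adjusted p = 0.0420, adjusted p = 0.517 with an estimated correlation). The protease call ended without 0 h replicate 1 or 3 or 1 h replicate 1 (adjusted p = 0.056, 0.12 and 0.062). The reference gene call ended without 0 h replicate 2 or 3 or 1 h replicate 1 or 3 (adjusted p = 0.057, 0.16, 0.10 and 0.074), and its median of 0.15 became −0.01 with FPKM scaled to a constant sum and −0.08 under quantile normalization.

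Lists without a camera call at 1 h still held called genes. Clock genes split, with 6 of 16 higher and 1 lower (6 and 2 adjusted over the list alone). *Cry2* (3.51), *Per1* (1.95) and *Bhlhe40* (1.89) rose, and *Ciart* (−0.89) fell. Prostaglandin genes rose in 4 of 15 cases (5 adjusted over the list alone), including the receptor genes *Ptger4* (3.82) and *Ptgfr* (1.79). Cytokine genes rose in 3 of 14 cases (3 higher and 1 lower adjusted over the list alone), led by *Tnfsf11* (3.33). A single gene was called higher of 30 S phase and mitosis genes (0 adjusted over the list alone, 2 at an unadjusted p below 0.05) and of 18 glycolysis genes (1 adjusted over the list alone). The former, *Pcna*, lost its call without 0 h replicate 2 or 3, 1 h replicate 3 or 6 h replicate 2 and with FPKM scaled to a constant sum or quantile normalized (adjusted p = 0.0529 to 0.116), and the latter, *Pfkfb3*, from its most abundant transcript row alone (0.1003). With FPKM scaled to a constant sum 4 S phase and mitosis genes were called lower. With limma, 0 members were called, over all genes or over the list alone, among 17 oocyte, 14 theca and stroma, 10 endothelial, 11 leukocyte, 4 erythroid, 9 surface epithelium and 13 mitochondrially encoded genes. At an unadjusted p below 0.05 there were 2, 1, 0, 1, 0, 0 and 0. For all these lists the camera adjusted p lay between 0.0591 and 0.924. Oocyte markers were called by camera without 0 h replicate 1 (adjusted p = 0.000458), 1 h replicate 2 (0.0377) or 6 h replicate 3 (0.0475), and S phase and mitosis genes, with a negative median, without 0 h replicate 2 (0.0366), 0 h replicate 3 (0.0443) or 1 h replicate 3 (0.00317). Prostaglandin genes were called without 0 h replicate 2 (0.0482), 1 h replicate 3 (0.0373) or 6 h replicate 2 (0.0458), clock genes without 0 h replicate 2 (0.0497), and cytokine and leukocyte genes without 1 h replicate 3 (0.0194 and 0.0177). Estradiol and glycolysis genes were called without 1 h replicate 2 (0.0121 and 0.0422). With FPKM scaled to a constant sum the medians of the clock, prostaglandin, glycolysis, estradiol, endothelial and mitochondrial lists turned from positive to negative.

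Among genes that met the rule for naming, which leaves out low, predicted and assembled genes, the lowest log2 changes at 1 h were in *Atf7ip* (−1.53), *Tmprss13* (−1.16), *Hist1h2an* (−0.97), *Zfp41* (−0.93), *Ciart* (−0.89), *Mtif3* (−0.89), *Repin1* (−0.88) and *Pias3* (−0.88). *Tmprss13*, a transmembrane serine protease gene, went from 12.6 ± 1.93 to 5.18 ± 1.54 FPKM. The fall of *Atf7ip* rests on 1 of its 8 rows, which averaged 71.2 FPKM at 0 h and was listed at 0 in the other groups. Its 0 h libraries measured 133, 173 and 52.1 FPKM, and the call ended without 0 h replicate 1 (adjusted p = 0.060) or 1 h replicate 3 (0.064). The calls of *Zfp41* (without 1 h replicate 1 or 3, adjusted p = 0.0504 and 0.0543) and *Mtif3* (without 0 h replicate 1 or 2, 0.058 and 0.057) ended as well. *Ciart*, *Repin1* and *Mtif3* were not called from their most abundant row alone (adjusted p = 0.31, 0.71 and 0.11).

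In all, limma called 2276 of 14535 genes between 1 h and 0 h, 1407 higher and 869 lower. A change of 2-fold or more was seen in 379 higher and 17 lower genes. The split depends on the scale: with FPKM scaled to a constant sum it was 1033 higher and 2594 lower, with a shift of the median gene of −0.15, though this setting also raised all values against the filter and the pseudocount (16050 genes tested). With FPKM scaled to the mean sum of the libraries, which leaves both on their scale (14553 genes tested), the split was 1002 and 2634 with a shift of −0.14, and under quantile normalization 1150 and 1237. The counts were lowest without 1 h replicate 3 (904 higher, 295 lower) and highest without 1 h replicate 2 (1601 and 1223). Lower calls numbered 407, 425 and 320 without 0 h replicates 1, 2 and 3 and 336 without 1 h replicate 1.

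**Figure D2:**
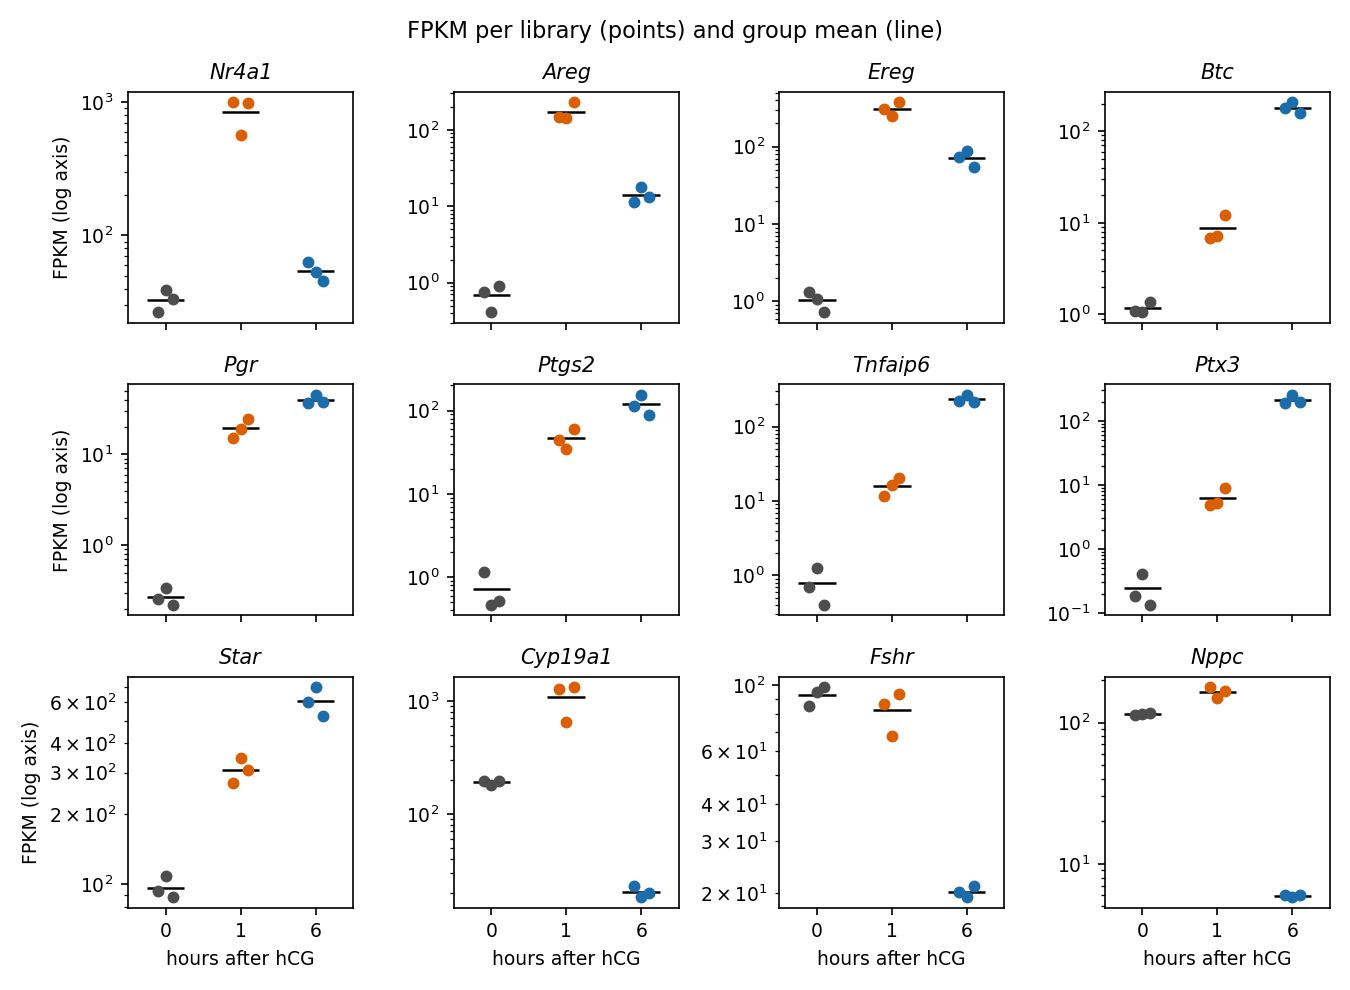
FPKM of 12 genes of the fixed ovulation list at 0, 1 and 6 h after hCG. The vertical axis is logarithmic, each point is a library and each line the mean of 3. *Nr4a1* averages 847 FPKM at 1 h and 53.8 at 6 h, *Ptx3* rises to 214 at 6 h, and *Cyp19a1* goes from 191 through 1074 to 20.5.

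The comparison of 6 h with 0 h describes the transcriptome further towards ovulation. Most genes of the cumulus matrix and of ovulation were higher than at 0 h, and most FSH-dependent genes were lower. The estrogen sulfotransferase gene *Sult1e1* (ENSMUSG00000029272, chromosome 5, 87575969 to 87591594) was listed at 0, 0.0567 and 0 FPKM in the 0 h libraries and measured 833 ± 127 FPKM at 6 h. The neurotensin gene *Nts* (ENSMUSG00000019890, chromosome 10, 102481756 to 102490486) measured 0.129, 0.243 and 0 FPKM at 0 h and 682 ± 53.3 at 6 h. *Lyve1*, a hyaluronan receptor gene, went from 0.647 ± 0.102 to 227 ± 37.5 FPKM (7.10 ± 0.14). The kinase gene *Prkg2* went from 0.498 ± 0.243 to 135 ± 27.8 FPKM (6.50 ± 0.16). The neuropeptide gene *Npy* was listed at 0 in all 3 libraries at 0 h and measured 53.5, 66.4 and 97.7 FPKM at 6 h.

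In the cumulus expansion list 10 of 11 genes were higher and 0 lower (10 adjusted over the list alone), with a median log2 change of 4.48. *Ptx3* reached 214 ± 34.3 FPKM (7.43 ± 0.20), *Tnfaip6* 234 ± 28.0 (7.06 ± 0.21), *Has2* 21.7 ± 4.93 and *Ptgs2* 119 ± 32.6. For cumulus expansion genes the camera adjusted p was 7.52e-07, and the adjusted p was 0.25 with an estimated correlation. Of the factors required for ovulation 16 of 18 rose and 2 fell (16 and 2 adjusted over the list alone). *Runx1* reached 368 ± 22.3 FPKM (4.36 ± 0.16), *Pgr* 39.8 ± 4.54 (5.00 ± 0.15), and *Cebpb* 268 ± 173, with a wide spread between libraries. For the ovulatory factors the camera adjusted p was 2.88e-06, and the adjusted p was 0.232 with an estimated correlation. Proteases and their inhibitors were higher in 12 of 19 cases and lower in 4 (12 and 4 adjusted over the list alone), with *Adamts9* at 2.68, *Adam8* at 2.52 and the inhibitor gene *Timp1* at 2.42. For proteases the camera adjusted p was 0.00439, and the adjusted p was 0.439 with an estimated correlation. Among EGF-like factors and receptors 5 of 10 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0544). *Btc* was at 181 ± 24.7 FPKM (6.38 ± 0.19), *Ereg* at 72.3 ± 16.4 and *Areg* at 14.1 ± 3.30. Leaving out 0 h replicate 2, 1 h replicate 3 or any 6 h library gave this list a camera call (adjusted p = 0.0353 to 0.0414).

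Estradiol synthesis and FSH-dependent genes fell in 20 of 21 cases, with 0 higher (20 adjusted over the list alone) and a median log2 change of −1.42. *Nppc* (ENSMUSG00000026241, chromosome 1, 86666291 to 86670571) had the largest fall of the named genes, from 115 ± 2.13 to 5.95 ± 0.132 FPKM (−4.06 ± 0.07, adjusted p = 4.90e-10). The inhibin beta B gene *Inhbb* went from 1239 ± 51.6 to 117 ± 15 FPKM (−3.40 ± 0.16). *Cyp19a1* went from 191 ± 8.0 to 20.5 ± 2.46 (−3.17 ± 0.23), *Fshr* from 93.0 ± 7.06 to 20.2 ± 0.861, and *Lhcgr* from 251 ± 28.5 to 110 ± 29.0. For the estradiol list the camera adjusted p was 9.63e-10, and the adjusted p was 0.232 with an estimated correlation. Outside this list the lowest changes among genes that met the rule for naming were in *Mro* (−3.86), the aldo-keto reductase gene *Akr1c14* (−3.28), *Tmprss13* (−3.09), *Ogdhl* (−3.00) and *Smim10l2a* (−2.99).

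Cholesterol synthesis genes rose in 17 of 23 cases with 0 lower (17 adjusted over the list alone), among them *Cyp51* (1.37 ± 0.11), *Idi1* (1.23 ± 0.10) and *Insig1* (1.17 ± 0.06). For cholesterol synthesis genes the camera adjusted p was 9.80e-06, and the adjusted p was 0.491 with an estimated correlation. The progesterone list had 9 of 14 members higher and 3 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.0805). *Star* stood at 606 ± 86.0 FPKM and the cholesterol exporter gene *Abca1* at 95.2 ± 10.1 from 20.9 ± 3.05, while *Lhcgr* fell. *Cyp11a1* was at 1187 ± 58.8 FPKM (0.49 ± 0.15, adjusted p = 0.0186), a call that ended without 0 h replicate 3 (0.055) or 6 h replicate 1 (0.053) or 2 (0.051). It also ended with FPKM scaled to a constant sum (0.054) and under quantile normalization (0.11). Prostaglandin genes went both ways, 7 of 15 higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.224). The synthase gene *Ptgs1* (3.19) and the transporter gene *Slco2a1* (3.12) rose.

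Immediate-early factors were still higher in 19 of 26 cases and lower in 1 (19 and 1 adjusted over the list alone), led by *Egr3* (4.60), *Ier3* (2.25) and *Fosl1* (2.16). For immediate-early factors the camera adjusted p was 4.13e-05, and the adjusted p was 0.333 with an estimated correlation. *Nr4a1* was at 53.8 ± 8.54 FPKM (0.69 ± 0.22), a call that ended without 0 h replicate 1 (adjusted p = 0.083) or 6 h replicate 1 (0.078) or 2 (0.054). *Fos*, at 176 ± 22.2 FPKM, did not pass (adjusted p = 0.825). Feedback regulators were higher in 18 of 21 cases and lower in 1 (19 and 1 adjusted over the list alone), with *Errfi1* at 4.36 and *Rgs2* at 2.54. For feedback regulators the camera adjusted p was 1.74e-06, and the adjusted p was 0.333 with an estimated correlation. S phase and mitosis genes fell in 12 of 30 cases and rose in 1 (12 and 1 adjusted over the list alone), with *Ccnb2* at −1.18 and *Mcm3* at −1.02. For S phase and mitosis genes the camera adjusted p was 0.0290, with an adjusted p of 0.828 with an estimated correlation. The call ended without 0 h replicate 1 (0.095) or 6 h replicate 1 (0.10) and under fry (0.103). Growth arrest genes rose in 7 of 12 cases and fell in 2 (8 and 2 adjusted over the list alone), with *Cdkn1a* at 2.39. For growth arrest genes the camera adjusted p was 0.0447, with an adjusted p of 0.353 with an estimated correlation, and 0.056 without 0 h replicate 1.

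Hypoxia and angiogenesis genes were higher in 13 of 18 cases and lower in 5 (13 and 5 adjusted over the list alone), with *Sphk1* at 3.74. For angiogenic genes the camera adjusted p was 0.0448, the adjusted p was 0.333 with an estimated correlation, and it was 0.054 without 0 h or 1 h replicate 1. Heat-shock genes were higher in 6 of 11 cases (6 adjusted over the list alone), with *Hsph1* at 1.47. For heat-shock genes the camera adjusted p was 0.0448, the adjusted p was 0.512 with an estimated correlation, and it was 0.116 without 0 h replicate 1 and 0.0501 without 0 h replicate 3. Unfolded protein response genes were lower in 8 of 15 cases and higher in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0744), with *Sdf2l1* at −1.26 and *Atf4* at 1.13. They were called without 1 h replicate 3 (0.0373), and the progesterone list without 6 h replicate 3 (0.0475). Clock genes split into 7 of 16 higher and 7 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.906), with *Per1* at 1.72 and *Ciart* at −2.13. Cytokine genes were higher in 7 of 14 cases (7 adjusted over the list alone; camera adjusted p = 0.0745), with *Nfkbia* at 1.60. Glycolysis genes were higher in 3 of 18 cases and lower in 8 (3 and 8 adjusted over the list alone; camera adjusted p = 0.355), with *Eno2* at 1.97 and *Pfkm* at −1.46. YAP targets were higher in 3 of 9 cases and lower in 3 (3 and 3 adjusted over the list alone; camera adjusted p = 0.843), with *Tead1* at 1.72 and *Ctgf* at −1.13, and their median of 0.07 became −0.02 with FPKM scaled to a constant sum. Reference genes were higher in 4 of 14 cases and lower in 2 (2 and 2 adjusted over the list alone; camera adjusted p = 0.412), and their median of 0.11 became −0.06 under quantile normalization. *Ywhaz*, often used as a reference, rose from 193 ± 5.60 to 833 ± 115 FPKM (2.09 ± 0.10).

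Markers of other cells moved at 6 h alongside these groups. Oocyte markers were higher in 14 of 17 cases and lower in 0 (15 adjusted over the list alone), with a median log2 change of 0.80. *Gdf9* went from 12.6 ± 3.18 to 24.9 ± 5.35 FPKM and *Padi6* from 5.97 ± 1.32 to 13.9 ± 3.51. For oocyte markers the camera adjusted p was 0.00220, and the adjusted p was 0.616 with an estimated correlation. Theca and stroma markers were lower in 6 of 14 cases and higher in 0 (6 adjusted over the list alone), with *Cyp17a1* going from 123 ± 32.3 to 21.9 ± 5.04 FPKM. For theca and stroma markers the camera adjusted p was 0.0369, with an adjusted p of 0.557 with an estimated correlation. That call ended without 0 h replicate 1 (0.064), 0 h replicate 2 (0.057) or 6 h replicate 3 (0.058). Endothelial markers were higher in 3 of 10 cases (3 adjusted over the list alone; camera adjusted p = 0.267), and erythroid markers lower in 2 of 4 (2 adjusted over the list alone; 0.252). Leukocyte markers were lower in 1 of 11 cases (0 adjusted over the list alone; 0.403) and surface epithelium markers higher in 1 and lower in 2 of 9 (0 and 1 adjusted over the list alone; 0.696). Of the mitochondrially encoded genes 1 of 13 was lower (0 adjusted over the list alone; 0.576). Several of these single calls ended when libraries were left out. *Hba-a1* lost its call without 0 h replicate 2 or 3, 1 h replicate 2 or 6 h replicate 1 or 3 (adjusted p = 0.0583 to 0.159), and *Lyz2* without 0 h replicate 2 (0.07003) or 6 h replicate 1 (0.0644). *Upk3b* lost it without 0 h replicate 1 or 2, 1 h replicate 1 or 6 h replicate 2 or 3 (0.0535 to 0.164). *Cdh1* lost it without 0 h replicate 2 or 3, 1 h replicate 1 or 3 or 6 h replicate 2 or 3 (0.0537 to 0.1397), and *mt-Co2* without 0 h replicate 2 or 3, any 1 h library or 6 h replicate 2 or 3 (0.0574 to 0.164).

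In all, limma called 8231 of 14535 genes between 6 h and 0 h, 4180 higher and 4051 lower. A change of 2-fold or more was seen in 1141 higher and 910 lower genes. All 3 libraries of either time lay above all 3 of the other for 64.9% of genes, where chance gives 10%. Leaving out any library kept both counts within 1.5 times, between 3351 and 4280 higher and between 3512 and 4126 lower.

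**Figure D3:**
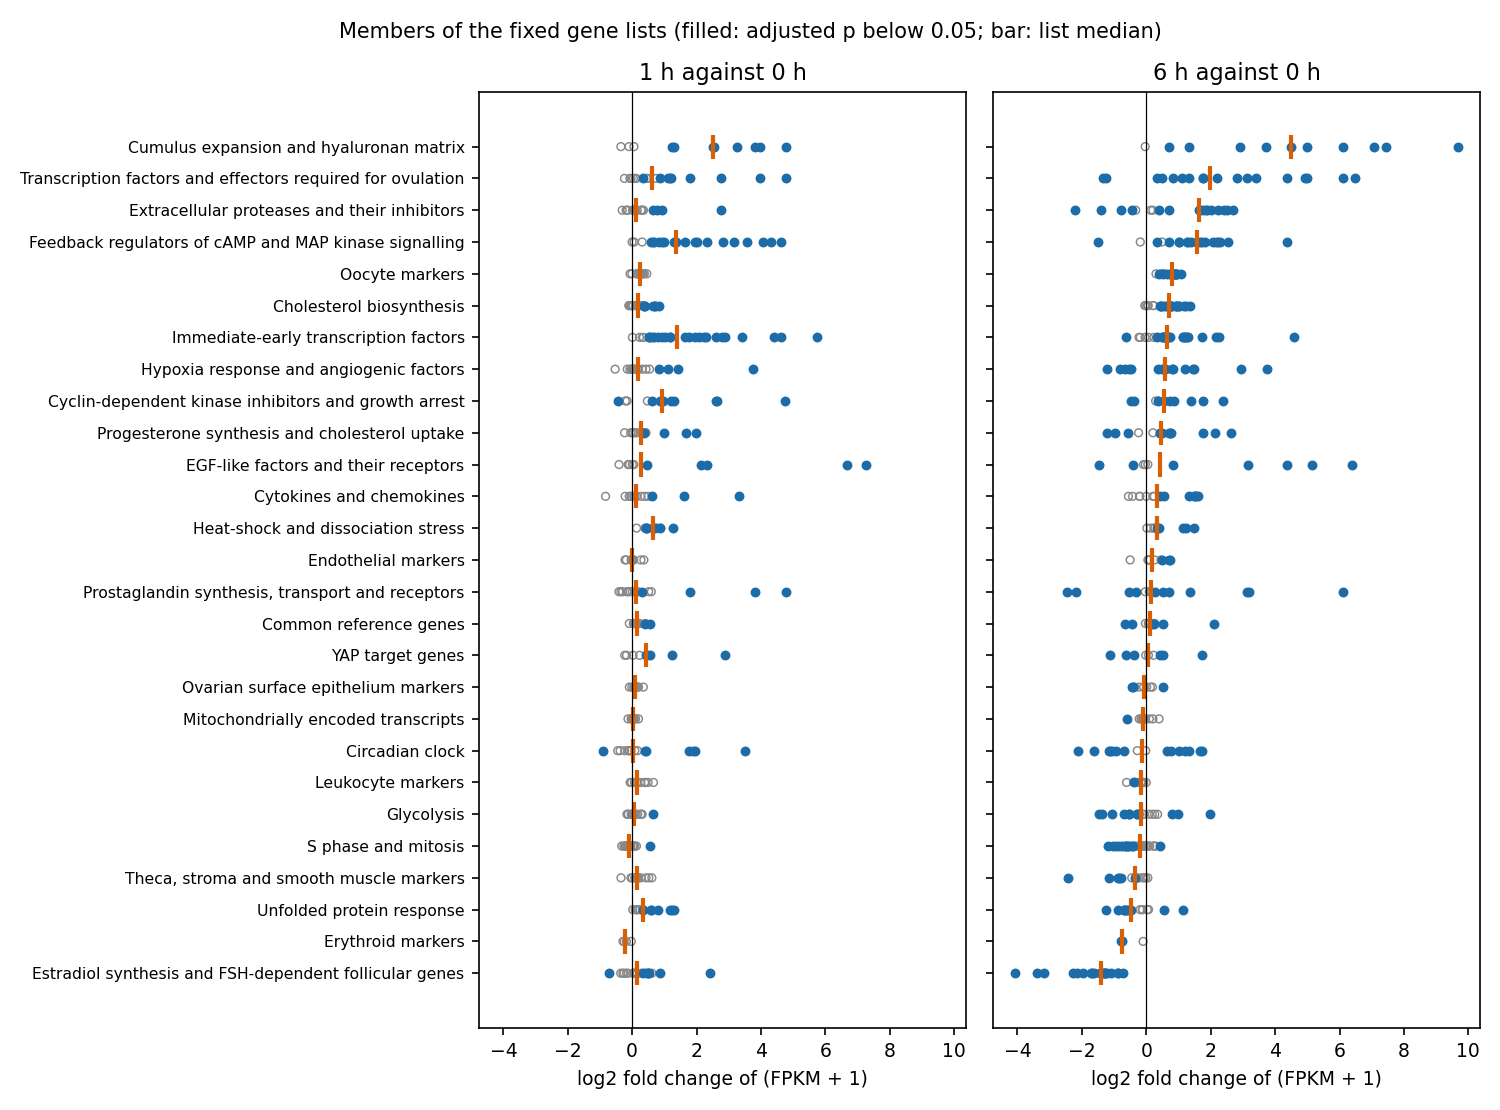
Log2 changes of the members of the 27 fixed gene lists at 1 h and at 6 h against 0 h. Each point is a gene, filled where its adjusted p was below 0.05, and each bar is the median of a list. The bar of the estradiol and FSH-dependent list lies at −1.42 at 6 h and that of the cumulus expansion list at 4.48.

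The comparison of 6 h with 1 h covers genes that kept rising or had come down, and also genes without a call at 1 h. Of the 1407 genes called higher at 1 h against 0 h, 395 were higher still at 6 h and 554 were lower than at 1 h. Among genes that met the rule for naming, the aromatase gene *Cyp19a1* had the lowest log2 change (−5.58 ± 0.23). It was followed by the chemokine receptor-like gene *Ccrl2* (−4.60), *Nppc* (−4.58), *Nr4a3* (−4.46), *Nr4a2* (−4.07), *Gadd45b* (−4.00), *Mro* (−3.98) and *Nr4a1* (−3.92). *Sult1e1* (8.36), *Nts* (7.16), *Lyve1* (7.06), *Prkg2* (6.01), *Npy* (5.05), the leptin receptor gene *Lepr* (4.98), *Ptx3* (4.91) and *Snap25* (4.79) were the highest under the same rule. *Lepr* went from 0.601 ± 0.0977 to 49.6 ± 7.19 FPKM. The EGF-like genes parted, with *Areg* (−3.51 ± 0.21) and *Ereg* (−2.09 ± 0.19) lower and *Btc* (4.25 ± 0.19) higher.

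Immediate-early factors were lower at 6 h than at 1 h in 17 of 26 cases and higher in 6 (17 and 6 adjusted over the list alone), with a camera adjusted p of 0.00362 and an adjusted p of 0.492 with an estimated correlation. Estradiol and FSH-dependent genes were lower in 20 of 21 cases (20 adjusted over the list alone), with a camera adjusted p of 1.00e-10 and an adjusted p of 0.232 with an estimated correlation. Unfolded protein response genes were lower in 13 of 15 cases and higher in 2 (13 and 2 adjusted over the list alone), with *Herpud1* at −1.45 and *Dnajb9* at −1.41. For unfolded protein response genes the camera adjusted p was 0.000180, and the adjusted p was 0.333 with an estimated correlation. Cumulus expansion genes were higher in 9 of 11 cases and lower in 1 (9 and 1 adjusted over the list alone), with *Alcam* at 4.58 and *Ptger4* at −3.12. For cumulus expansion genes the camera adjusted p was 0.000279, and the adjusted p was 0.333 with an estimated correlation. Factors required for ovulation were higher in 13 of 18 cases and lower in 3 (13 and 3 adjusted over the list alone), with a camera adjusted p of 0.00429 and an adjusted p of 0.374 with an estimated correlation. Cholesterol synthesis genes were higher in 16 of 23 cases (17 adjusted over the list alone), with *Lss* at 0.89. For cholesterol synthesis genes the camera adjusted p was 0.000178, and the adjusted p was 0.512 with an estimated correlation.

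Proteases were higher in 11 of 19 cases and lower in 6 (11 and 6 adjusted over the list alone). For proteases the camera adjusted p was 0.0394, with an adjusted p of 0.517 with an estimated correlation, 0.065 without 1 h replicate 2 and 0.068 without 6 h replicate 1. Oocyte markers were higher in 8 of 17 cases (12 adjusted over the list alone). For oocyte markers the camera adjusted p was 0.0194, with an adjusted p of 0.759 with an estimated correlation, 0.053 without 1 h replicate 2, 0.058 without 6 h replicate 3 and 0.0893 under fry. Theca and stroma markers were lower in 9 of 14 cases (10 adjusted over the list alone), with a camera adjusted p of 0.0104 and an adjusted p of 0.512 with an estimated correlation. For the remaining lists camera gave adjusted p-values from 0.0985 to 0.975. S phase and mitosis genes were called without 1 h replicate 2 (0.0215) or 6 h replicate 3 (0.0273), glycolysis genes without 1 h replicate 2 (0.0452) and leukocyte markers without 1 h replicate 3 (0.0177). The hypoxia and angiogenesis list had a median of −0.07 with a positive mean and test, and the feedback list a median of 0.18 with a negative mean and test. For reference genes the mean and the test differed in sign. In all, 7783 of 14535 genes were called by limma, 3879 higher and 3904 lower, of which 863 and 901 by 2-fold or more.

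Genes were then sorted by their calls at all 3 times. Of the 1407 genes higher at 1 h, 554 were lower again at 6 h than at 1 h and 934 were higher than 0 h at both times, with 135 in both classes. *Nr4a1* and *Gadd45b* belonged to the first and *Ptx3* and *Star* to the second, and *Nr4a1*, still called higher at 6 h than at 0 h, belonged to both. Another 3170 genes, *Lepr* and *Lyve1* among them, were higher at 6 h without a call at 1 h. Of the 869 genes lower at 1 h, 344 were higher again at 6 h than at 1 h and 444 stayed lower than 0 h, and 3487 were lower at 6 h without a call at 1 h. The classes of genes that fell at 1 h changed much in size whichever 0 h or 1 h library was left out. Transient falls numbered 183, 162 and 137 without 0 h replicates 1, 2 and 3, and 122, 584 and 114 without 1 h replicates 1, 2 and 3. Sustained falls numbered 199, 232 and 158 without those 0 h replicates, and 197 and 180 without 1 h replicates 1 and 3. Transient rises numbered 355 without 1 h replicate 3. These comparisons share libraries. In a simulation all 9 libraries were drawn from a common mean per gene, and each of the 4 classes that combine 2 calls held 0 genes. With no gene truly changed a class that needs 2 calls is bound to be near empty. The simulated counts therefore do not show how sharing libraries affects the classes when many genes change. Independent lists of the same sizes would give 378, 405, 232 and 242 in the order transient rise, sustained rise, transient fall and sustained fall. The log2 changes at 1 h and 6 h against 0 h had a Pearson's r of 0.427 across genes, against 0.501 in the simulation, and a covariance of 0.152 against 0.0158. The simulated covariance is what the spread between the 0 h libraries gives, and a shift common to all 0 h libraries was not simulated. The sustained classes share the 0 h libraries and the transient classes the 1 h libraries. With 3 libraries per time neither could be split. Part of the excess of the classes over independent lists may therefore come from shared libraries.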

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

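The tests on replicate 2 at 1 h and on the oocyte markers were chosen only after the results were seen.

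For 8 named genes the change at 1 h and the change at 6 h, both against 0 h, were called in opposite directions. The 6 h minus 1 h differences given here follow from that choice of genes, so no p-value is set beside them. The aromatase gene *Cyp19a1* rose and then fell below its 0 h level, with a difference of −5.58. *Ccrl2* differed by −4.60, *Nppc* by −4.58, and the clock genes *Per2* and *Nr1d2* by −2.45 and −2.02. The rise of *Nr1d2* at 1 h lay close to the threshold (0.40 ± 0.12, limma adjusted p = 0.0495). The nuclear receptor gene *Nr5a2* differed by −2.19 and the stress gene *Herpud1* by −1.45. *Cdkn2d*, a cell cycle inhibitor gene, went the other way, lower at 1 h and higher at 6 h, with a difference of 1.81. Among all genes, 120 rose at 1 h and lay below 0 h at 6 h, and 76 fell and then rose above it. Independent lists of the same sizes would give 392 and 250, and sharing the 0 h libraries may lower such counts.

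Replicate 2 at 1 h lay nearer to the 0 h libraries than the other two 1 h libraries, with a median response of 0.608 relative to them over 419 genes. The genes were chosen from the other two libraries, and replicates 1 and 3 measured the same way gave 0.996 and 1.34. Later sampling would leave genes already back near the 0 h level by 6 h low and genes that rise further at or above the others, but both were low, at 0.565 (95% interval 0.520 to 0.598, 156 genes) and 0.729 (0.653 to 0.815, 75 genes). An admixture of unstimulated cells needs both gene classes to be alike. Against replicate 3 alone they gave 0.542 (95% interval 0.484 to 0.568) and 0.628 (0.566 to 0.709), intervals that barely overlap. Against replicate 1 alone they gave 0.586 and 0.882, with intervals apart. Earlier sampling would lower the genes that rise further more, and in both comparisons they were lowered less. Both explanations stay open, because the intervals still overlap slightly against replicate 3. The gene classes were also set by the rise in replicates 1 and 3, by which the response of replicate 2 is divided. Spread in that rise can push the classes apart in the direction seen, so the gap between them cannot decide. The intervals also resample genes and leave out the variation between libraries (replicate 1 against replicates 2 and 3 gave 1.10 and 0.848). No biological explanation was tested.

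Oocyte markers were higher at 6 h than at 0 h in 82.4% of cases (14 of 17), as more oocyte RNA in the 6 h preparations would give. This share is the observation that prompted the explanation, so it is no test of it. Their summed FPKM was 70.7 to 111 at 0 h, 88.4 to 113 at 1 h and 131 to 201 at 6 h. A lower share of granulosa cells would raise the markers of all other cells alike. The medians of oocyte and of theca and stroma markers instead lay 1.15 apart (0.80 and −0.34, two-sided permutation p = 2e-05). The permutation treats genes as independent, though the estimated inter-gene correlation was 0.753 for oocyte and 0.298 for theca and stroma markers. It was also chosen after their opposite directions were seen, so this p overstates the contrast. Endothelial, leukocyte, erythroid and surface epithelium medians were 0.18, −0.16, −0.74 and −0.08. More oocytes, or a change within them, may account for the rise, and the design cannot separate these. A lower share of granulosa cells is not excluded either, since changes within theca and stroma cells were not tested.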

How the results depend on the processing

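The 7 alternatives chosen only after the data were seen were median-ratio scaling, scaling to a constant sum or to the mean sum of the libraries, quantile normalization, a stricter filter, protein-coding genes alone and the most abundant transcript row. Of 253 named gene results under up to 22 alternatives, 166 had the same call and direction in every alternative. Over all combinations of gene result and alternative, 276 lost the call, 6 gained it and 0 reversed. Of the losses, 67 came from the fold minimum of 2 and 84 from the treat test. A result lost under either of these settings is not among the 166. A fold of 2 or more left 379 and 17 genes higher and lower at 1 h against 0 h, 1141 and 910 at 6 h against 0 h and 863 and 901 at 6 h against 1 h. The treat test left 270 and 1, 1156 and 886, and 854 and 846, since both settings ask for a larger change by construction. Scaling to a constant sum gave 2594 lower genes at 1 h and scaling to the mean sum 2634, since both remove the higher FPKM sums at 1 h by construction. With an estimated correlation camera called 0 of the 81 list tests and 12 of the 81 had an unadjusted p below 0.05, against 36 calls with the preset correlation and 50 with fry. Fry lost 2 of the camera calls and called 15 list tests in the same direction that camera had not called. Among these 15 at 6 h against 0 h were EGF-like factors (fry adjusted p = 2.10e-05), prostaglandin (6.94e-06) and progesterone genes (0.000309). Clock genes at 1 h were another (0.000661). The prostaglandin list at 6 h against 1 h turned upward under fry (adjusted p = 0.000764), and the cause was not tested. Leaving out each library in turn gave 904 to 1601 higher and 295 to 1223 lower genes at 1 h, 3351 to 4280 and 3512 to 4126 at 6 h against 0 h, and 3028 to 3837 and 3346 to 3866 at 6 h against 1 h. It gave 31 to 42 list changes. Transient rises numbered 355 to 668, sustained rises 647 to 1064, late rises 2529 to 3531, transient falls 114 to 584, sustained falls 158 to 585 and late falls 3072 to 3801, with fewer libraries by construction.

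The labels do not say whether the replicate numbers pair the libraries. Same-numbered libraries had correlated deviations of −0.078 to 0.147, over 0.1 in 4 of 9 pairs, and 12 of 18 best matches were the own number, a hint from the data and not the design. With the replicate number as a block, 1306 and 685 genes were higher and lower at 1 h, 4090 and 3999 at 6 h against 0 h, and 3777 and 3855 at 6 h against 1 h. The block called *Cyp11a1* at 1 h (0.041) and the leukocyte list at 6 h against 1 h (0.0356). It lost *Cdh1* (0.062), *mt-Co2* and the angiogenesis list (0.0625) at 6 h against 0 h, and changed no other call of a named gene or list. Count-based alternatives that were fixed beforehand were not run, because the tables hold FPKM. The depth is unknown, so limits that counting error sets could not be given.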

Other observations

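The tests on nested genes, peptide genes and transcript rows, the look at lymphatic genes and the transcript shares were chosen only after the results were seen. The regrouping of libraries was set beforehand.

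Several genes for secreted peptides rose at 6 h. *Nmu* reached 45.6 ± 5.28 FPKM from 0.259 ± 0.141 at 0 h, *Adcyap1* 51.1 ± 21.5 from 0.379 ± 0.190, *Penk* 76.1 ± 7.94 from 4.13 ± 0.364 and *Tac1* 40.5 ± 8.67 from 4.43 ± 0.712, all called by limma. The proglucagon gene *Gcg* was listed at 0.0714, 0 and 0 FPKM in the 0 h libraries and measured 15 ± 1.77 FPKM at 6 h. *Lyve1*, also a marker of lymphatic endothelium, rose without the other lymphatic genes looked at: *Flt4* (−0.80 ± 0.12) and *Ccl21a* (−0.84 ± 0.15) fell, and *Pdpn* did not pass (adjusted p = 0.402).

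Whether peptide precursor genes rose more often at 6 h than other genes was not settled. A list of 68 was written after some were seen, 28 were tested, and 13 rose by 2-fold or more, but 11 of the 28 had been noticed beforehand and the filter admits genes by their 6 h values. Among protein-coding genes without the filter, 6 of 44 not noticed beforehand rose (13.6%), against 955 of 18258 outside the list (5.23%, two-sided Fisher's exact p = 0.0265). Among those with 1 FPKM or more in all 0 h libraries, 1 of 5 rose, against 733 of 11700 (6.26%, two-sided Fisher's exact p = 0.277), which is too few to tell. Over all 28, 16 were called higher and 5 lower, *Nppc* among the latter.

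Genes nested inside genes that rose 2-fold or more at 1 h rose with their hosts in 12 of 13 cases, with a median of 1.68 against −0.08 for 642 nested in hosts not called. The permutation p was 1e-05, the smallest that 100000 permutations can give. Reads from unspliced host RNA would give this pattern, but the test was chosen after the pattern was seen and cannot single out that cause. *Gm17087* (chromosome 17, 8565852 to 8566950, inside *Pde10a*) had a log2 change of 6.54 and 4.1 times the FPKM of its host at 1 h, which decides nothing, since no bound on unspliced reads is known. Activation of the whole region could not be judged. Neighbours were counted within 100 kb, without overlap, and only if non-coding or with a Gm-number or Rik symbol. These hosts had 2 such neighbours (median −0.14). Among 86 such neighbours of 273 induced genes the median was 0.03 (95% interval −0.07 to 0.18), and 14 were called higher. Over all genes tested at 1 h, 1407 of 14535 were called higher. Other protein-coding neighbours, such as *Areg* near *Ereg*, were not counted.

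A limma F test for unequal log2(FPKM + 1) changes between transcript rows covered 5491 genes with more than 1 row that passed the filter. At 1 h against 0 h, 6 h against 0 h and 6 h against 1 h it called 152, 591 and 684 genes. It does not test shares: with the added 1, rows of unlike level can differ in this change while their shares stay the same. The first row of *Pgr* held 77.6 ± 2.6% of its FPKM at 1 h and 33.3 ± 8.7% at 6 h (SD, n = 3).

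The 6 libraries of each comparison were also split into other groups of 3. In each comparison 1 of 10 splits, the real split, called as many genes. The real values were 2276, 8231 and 7783 genes and the highest of the other splits called 1 gene, but 10 splits are too few for a share below 0.05.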
